A study of Mus musculus with 2 samples.

How the data were processed

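H3K4me3 ChIP-seq peaks were analysed from kidneys of mouse embryos at day 14.5 (a cross of B6 substrains, healthy, both sexes pooled). Per the labels, the series holds 2 libraries numbered as biological replicates 1 and 2 of 1 group, with a fragment size range of 300 to 500 bp. The labels give each replicate its own biosample and both the same donor entry. With 1 group there was no test between conditions, no pairing and no batch to examine.

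The deposited files are 4 peak lists on mm10, described here from the submitters' file listings. The list of each replicate was derived from that replicate's filtered alignments and control files, the pooled list from the alignments of both replicates with the controls. The replicated list was derived from the pooled list and the lists of both replicates. The aligner, the peak caller, its version, its threshold and the rule of replication are not given in the sources used here. Checked on the files, all 23942 replicated peaks had the position of a pooled peak, and 21668 of them were overlapped by 1 bp in both replicate lists. The 3500 pooled peaks left out had a median -log10 q of 2.18 against 86.8 for those kept. The authors' lists give a signal value per peak, in this file format a measure of enrichment whose scale is not given in the sources used here. This deposited signal is not scaled between lists, so it was used to rank and describe peaks. Differences of its log2 between the replicates are described without a test. The lists also give the authors' -log10 p and -log10 q per peak, of which -log10 q served as a stricter filter. The deposited display score was not used further. The comparison plan had named the signal a fold enrichment, and the same ranks and log2 differences were computed on the deposited signal. No file lists read counts, so depth per library is unknown and no counting interval could be given. The number, width and signal of the peaks are all that shows the sensitivity of each library.

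Gene models were GENCODE release M21 on the same assembly (GRCm38, mm10), and no peak ran past a chromosome end. Peaks on unplaced or unlocalised scaffolds were left out of overlaps and gene-level comparisons (25 peaks of replicate 1, 12 of replicate 2 and 11 of the replicated list). A promoter was the window of 1 kb on either side of any annotated TSS of a gene, and a gene had a promoter peak if a peak overlapped a window by at least 1 bp. The height of a promoter was the highest signal among its peaks, averaged as log2 over the replicates for genes with a peak in both lists. A domain was a run of peaks separated by at most 1 kb, and the width at a gene was that of the widest domain overlapping a window. A peak that covers several genes gives them the same height and width. Distal peaks lay over 2.5 kb from every TSS. The CpG observed/expected ratio was computed from the genome sequence over peaks and, for promoters, over 1 kb on either side of the gene's 5′ end. The broadest domains were the 5% widest distinct promoter domains of protein-coding genes.

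Random placements of peaks (100, bedtools shuffle within chromosomes, outside assembly gaps of at least 1000 bp) gave the background of overlaps and of the promoter share, with one-sided permutation p. Shares of list members were tested with Fisher's exact test, two-sided, against all other protein-coding genes. Heights and widths of a list were placed as the percentile of its median among 10000 random lists of the same size drawn without replacement from the measured genes. Benjamini-Hochberg adjustment, with a threshold of 0.05, ran over 29 lists for peak presence. For heights (21 lists) and widths (22 lists) it ran over the lists with at least 5 measured members. For the broadest domains it ran over the 27 lists with at least 1 member that had a promoter domain. The alternatives of that last test used lists with at least 5 such members. All such tests compare genes, not samples. The mean heights of Hox paralog groups were compared with an exact permutation test. Widths of named genes are given as mean ± SD over the 2 replicate lists. On simulated data for 21938 genes, lists of 20 members from a set of genes with raised peak presence passed an unadjusted p of 0.05 in 100% of draws, against 3% for unchanged lists. On 14639 genes, lists of 20 members with widths scaled by 1.5 passed in 89% of draws and unchanged lists in 3%. Presence and widths were assigned to genes at random, without regard to CpG content. These shares therefore do not describe lists that differ from other genes in CpG content. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and bedtools 2.31.1 were used.

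The 29 gene lists, their tests, the rule for named genes and all alternatives but 2 were fixed before the data were examined. The comparison within gene families and the intervals from resampled members were chosen after the widths had been seen. The lists cover nephron progenitors, ureteric bud, early nephron, stroma, podocytes, endothelium, mature tubule transport, mesangium with vascular smooth muscle and renin lineage. They also cover macrophages and leukocytes, erythroid cells, neurons and neural crest, adrenal and gonad, germ line, regulators of other lineages, differentiated genes of other organs, housekeeping, cell cycle, signalling, CAKUT genes, cystic kidney and cilium, imprinted genes, Y-linked genes. Large families are ribosomal proteins, Hox genes, olfactory and vomeronasal receptors, keratin-associated proteins, KRAB-type zinc finger names (a pattern of gene names, not a test for the domain) and histone genes. One erythroid gene, Ahsp, was not found in the annotation under that name, and 4 imprinted genes are non-coding and stayed out of the tests. Some genes stand in more than 1 list. The named genes are a fixed set, the up to 3 highest members of each list and up to 2 members without a peak in alphabetical order. They also include the genes at the 10 broadest domains and 10 highest peaks, those nearest to the 5 highest distal peaks and the 10 with the largest difference between replicates among genes with a signal over 5. Klc3 and Eif2s3y, outside this rule, were chosen after their values were seen. Alternatives changed 1 choice at a time: each replicate's list alone, the pooled list, -log10 q of at least 2 or 5, an overlap of 50% of both peaks, promoter windows of 500 bp and 2.5 kb. Others were the 5′ end of the gene only, merging of touching peaks only or across 2 kb, distal peaks over 10 kb from a TSS, signal times width, and random lists matched on 5 classes of the promoter CpG ratio. Domains that hold the TSS of 1 protein-coding gene, and lists without Hox genes, were added after seeing the data.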

Results

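Trimethylation of lysine 4 of histone H3 (H3K4me3), a histone mark known from gene promoters, was profiled by chromatin immunoprecipitation and sequencing in kidneys of mouse embryos at day 14.5. At this stage the kidney holds self-renewing nephron progenitors, the branching ureteric bud, stroma and forming nephrons side by side. The libraries were 2 biological replicates of 1 group, each made from kidneys pooled from embryos of both sexes, so the data hold no comparison between conditions. The comparisons are between the replicates, and between groups of genes within this tissue. On the mouse assembly mm10, the list of replicate 1 held 30291 peaks covering 32.7 Mb. The list of replicate 2 held 30299 peaks covering 39.2 Mb. The authors' list called on both replicates pooled held 27442 peaks. Their list of replicated peaks, used for the gene-level comparisons, held 23942 peaks covering 36.7 Mb. Read numbers per library were not given in the sources used here, so the depth behind each peak is unknown.

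Regulators of each main compartment of the embryonic kidney carried a promoter peak in both replicates. Among them were Six2, Cited1, Wt1, Pax2, Sall1 and Eya1 of the nephron progenitors, Ret, Gata3 and Wnt9b of the ureteric bud, Foxd1 and Tbx18 of the stroma. The endothelial gene Pecam1 and the podocyte gene Nphs1, which encodes nephrin, had one too. No promoter peak was found in either replicate at Slc34a1 (phosphate transporter of the mature proximal tubule), Umod (uromodulin of the thick ascending limb), the leukocyte gene Ptprc or the liver gene Alb. Of the peaks of replicate 1 on assembled chromosomes, 82.5% were overlapped by at least 1 bp by a peak of replicate 2, against a mean of 3.0% when the second list was placed at random 100 times. In the other direction the share was 73.5% against 2.99%. The one-sided permutation p of 0.0099 in both directions is the smallest that 100 placements can give. Of all bases covered in either replicate, 73.6% (30.5 Mb) were covered in both. The peaks found in 1 list only were narrower, with a median width of 232 bp for the 5304 peaks of replicate 1 and 261 bp for the 8013 peaks of replicate 2, against 1081.5 and 1484 bp for the shared peaks. A -log10 q of at least 5 was reached by 1.17% of those of replicate 1 (62) and 21.1% of those of replicate 2 (1687). The authors' signal value, used here to rank and describe peaks, had a median of 6.60 in replicate 1 and 11.4 in replicate 2.

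The rank order of promoters by signal was largely kept between the replicates. Across 14520 protein-coding genes with a promoter peak in both lists, Spearman's rho was 0.897 (95% bootstrap interval 0.892 to 0.902). Across 24962 shared peaks it was 0.750. These correlations run across genes or peaks, which are not independent replicates. Values of replicate 2 were higher by a median of 1.02 on the log2 scale, with an SD of 0.32 over genes. Six2 had a signal of 15.5 in replicate 1 and 27.7 in replicate 2, Wt1 16.7 and 51.2, Pax2 20.9 and 41.6, Nphs1 3.33 and 8.20, and Actb (beta-actin) 34.3 and 74.4. The genes farthest from the common shift were Lypd3 (10.3 and 3.22, a log2 ratio of -2.70 after centring on the median) and Astl (2.79 and 32.0, 2.49). They were followed by Hes2 (-2.01), Dmpk (1.79), Rnf5 (1.70), Prkag3 (-1.67), Fgf4 (-1.66), Ehbp1l1 (1.60), Snx31 (-1.5) and Clec11a (1.5). Both replicates gave close domain widths at Astl (2218 and 2244 bp), Dmpk (4178 and 4384 bp) and Clec11a (2190 and 2391 bp). Widths at the others of these genes were not compared. A height takes the highest peak that overlaps a window, so a domain split differently into peaks could give such ratios, which was not tested. The highest promoter signals over both replicates were at Wbp11 and BC049715, which share 1 peak, Arid1a, Dnajc11, Ankrd11, Gnb1, Atxn2l, Marcksl1, Acbd3 and Csnk1d. They lay between 37.8 and 40.9 in replicate 1 and between 72.6 and 77.9 in replicate 2.

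**Figure D1:**
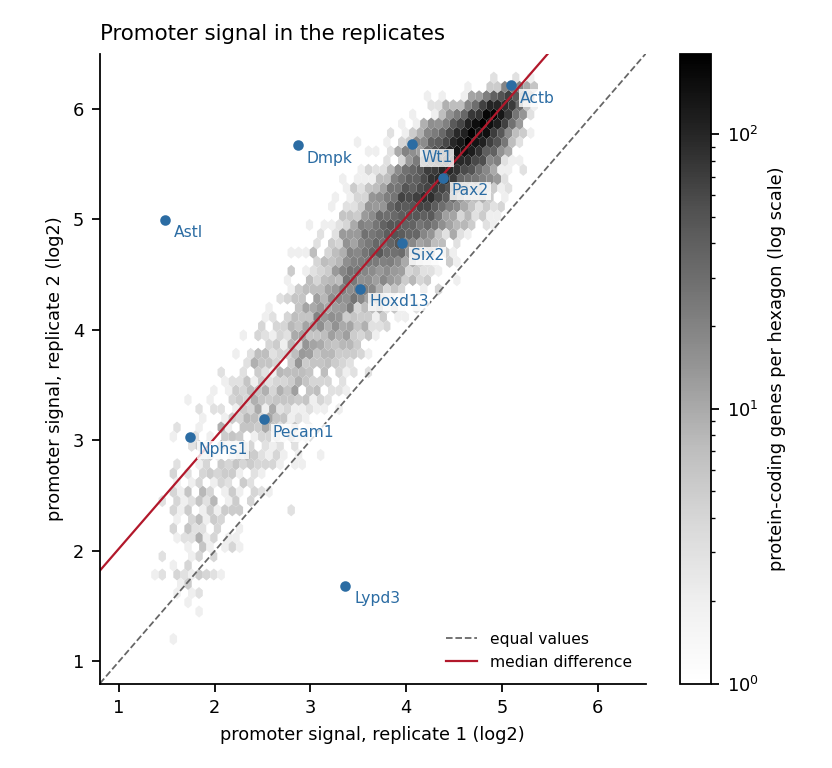
Highest signal value of the authors' peaks within 1 kb of a transcription start site in replicate 1 (x axis, log2) and replicate 2 (y axis, log2) for 14520 protein-coding genes, with genes per hexagon in grey on a log scale and genes named in the text as points. The bulk of genes lies along the solid line, 1.02 above the dashed line of equal values, while Lypd3 lies below it and Astl and Dmpk lie above it.

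Replicated peaks lay mainly at promoters. Of the 23931 replicated peaks on assembled chromosomes, 17086 (71.4%) lay within 1 kb of an annotated transcription start site (TSS), against a mean of 10.4% over 100 random placements (one-sided permutation p = 0.0099, the smallest that 100 placements can give). Another 1737 peaks (7.26%) lay between 1 and 2.5 kb from a TSS, and 5108 (21.3%) lay farther away, 2316 of them within a gene body and 2792 between genes. Promoter peaks had a median width of 1751 bp, a median signal of 28.2 and a median CpG observed/expected ratio of 0.59, against 579 bp, 5.14 and 0.47 for distal peaks. The 5 highest distal peaks overlapped no annotated gene. They lay on chromosome 8 at 69715367 to 69717621 (5769 bp from the TSS of Zfp869), chromosome 9 at 32031565 to 32034230 (83239 bp from Arhgap32), chromosome 1 at 171037665 to 171038762 (19293 bp from Fcgr4), chromosome 9 at 67631843 to 67634726 (73581 bp from Tln2) and chromosome 12 at 8640354 to 8641722 (33097 bp from Pum2). Their signals ranged from 25.5 to 31.5 in replicate 1 and from 45.7 to 57.1 in replicate 2. The number of distal peaks depended on the definition: 2580 replicated peaks lay over 10 kb from every TSS, and the lists of single replicates held 8108 (replicate 1) and 7705 (replicate 2) peaks over 2.5 kb away.

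A replicated promoter peak was found at 14639 of 21938 protein-coding genes (66.7%). The share was 25.5% for long non-coding RNA genes, 9.71% for those over 2.5 kb from any protein-coding TSS, and 2.42% for pseudogenes. It followed the CpG content of the promoter: over 5 classes of equal size, from the lowest to the highest CpG observed/expected ratio, the shares of protein-coding genes with a peak were 8.0%, 37.8%, 89.9%, 98.6% and 99.4%. Of 29 gene lists, 17 had a higher share of marked members than the other protein-coding genes and 9 a lower one (Fisher's exact test, two-sided, Benjamini-Hochberg over 29 lists). These tests compare genes, which are not independent of each other, and do not compare samples.

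In 6 lists of kidney cell types every member had a replicated promoter peak. This held for 17 of 17 nephron progenitor genes, 20 of 20 ureteric bud genes, 18 of 18 genes of the early nephron (renal vesicle to S-shaped body), 18 of 18 stroma genes, 14 of 14 podocyte genes and 16 of 16 endothelial genes. Adjusted p lay between 0.000968 and 0.00898 (Fisher's exact test). The highest signals within these lists were at Hoxa11, Hoxd11 and Itga8 (nephron progenitor), Etv5, Sox9 and Spry1 (ureteric bud), Notch2, Jag1 and Cdh6 (early nephron), Nr2f1, Pbx1 and Fat4 (stroma), Vegfa, Foxc2 and Cd2ap (podocyte), and Egfl7, Cldn5 and Kdr (endothelium). Complete lists were also found for 27 of 27 signalling genes of kidney development (highest at Fgfr2, Notch2 and Fgf20), 20 of 20 genes of cystic kidney disease and the cilium (Glis2, Pkd2, Ift140), 18 of 18 housekeeping genes (Actb, Eef2, Ywhaz), 18 of 18 cell cycle genes (Mki67, Cdk1, Rrm2) and 21 of 21 protein-coding imprinted genes (Gnas, Igf2r, Inpp5f). Adjusted p lay between 0.000113 and 0.00120 by the same exact test. In the list of replicate 1 alone, the stroma, signalling and cystic kidney lists had 17 of 18, 26 of 27 and 19 of 20 members marked. Of the genes of congenital malformations of the kidney and urinary tract (CAKUT), 30 of 32 were marked (adjusted p = 0.000991, Fisher's exact test), without a peak at Agt and Ren1 of the renin-angiotensin system. Hox genes (38 of 39, all but Hoxc12), ribosomal protein genes (91 of 95), genes with KRAB-type zinc finger names (344 of 391), histone genes (58 of 68) and developmental regulators of other lineages (21 of 24) also lay above the background. Adjusted p were 1.58e-05, 3.81e-11, 1.48e-21, 0.0012 and 0.0338 (Fisher's exact test).

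Genes of differentiated tubule function, blood cells and other organs were marked less often than other genes. Of 28 transport genes of the mature tubule, 9 had a peak (32.1%, adjusted p = 0.000532, Fisher's exact test). The highest signals were at Lrp2 (the endocytic receptor megalin), Ggt1 and Slc26a4, and the water channels Aqp1 and Aqp2 had no peak. None of 16 macrophage and leukocyte genes had a replicated peak (adjusted p = 1.08e-07, Fisher's exact test), Adgre1, Aif1 and Ptprc among them, although 2 members had a peak in the list of replicate 1. Of 14 erythroid genes 4 were marked, led by Klf1, Epor and Gypa. The haem synthesis gene Alas2 and Epb42 had no peak. Of 14 adrenal and gonad genes 5 were marked, led by Fdx1, Foxl2 and Gata4. Of 18 germ line genes 4 were marked, led by Tdrd6, Dazl and Dmrt1. The adjusted p of these lists were 0.005, 0.0239 and 0.000408 (Fisher's exact test). Of 24 differentiated genes of other organs, 5 had a peak (adjusted p = 1.9e-05, Fisher's exact test). The highest signals were at Ckm, Mbp and Krt1, and Acta1 and Afp had none. A TSS of a neighbouring gene, Klc3, lay in the domain at Ckm or within 1 kb of it. Of 1093 olfactory receptor genes 3 were marked, of 327 vomeronasal receptor genes 1, and of 54 keratin-associated protein genes none. Genes of neurons and neural crest (12 of 16), of the mesangium, vascular smooth muscle and renin lineage (10 of 12) and on the Y chromosome (4 of 10) did not pass the threshold. They gave adjusted p of 0.602, 0.371 and 0.10 (Fisher's exact test).

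Several of these calls ended when promoter CpG content was matched. Against 10000 random lists drawn from the same 5 classes of the CpG ratio, 5 lists stayed higher (stroma, endothelium, signalling, imprinted genes and KRAB-type zinc finger names) and 7 were lower. Among the 7 were Y-linked genes (40% against 70%, adjusted permutation p = 0.00896), which had not passed before, and histone genes. The calls of the nephron progenitor, ureteric bud, early nephron, podocyte, mature tubule, erythroid, adrenal and gonad, and other-organ lists ended, with adjusted permutation p of 0.533, 0.239, 0.274, 0.0781, 0.239, 1, 1 and 0.301. Those of the housekeeping, cell cycle, CAKUT, cystic kidney, ribosomal protein and Hox lists ended as well (adjusted permutation p between 0.0651 and 1). The nephron progenitor, ureteric bud, early nephron, podocyte, housekeeping, cell cycle and cystic kidney lists stood at 100%, the highest share possible. The medians of their matched lists were already 85.7% to 100%, so not even the highest share kept these calls. For these lists the matched test does not decide whether CpG content accounts for the share. Histone genes, higher before, had 85.3% against 97.1% in matched lists, and the call of developmental regulators of other lineages ended in 6 of 8 alternatives. With only the 5′ end of each gene the podocyte and endothelial calls ended, and with a window of 2.5 kb the adrenal and gonad call.

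**Figure D2:**
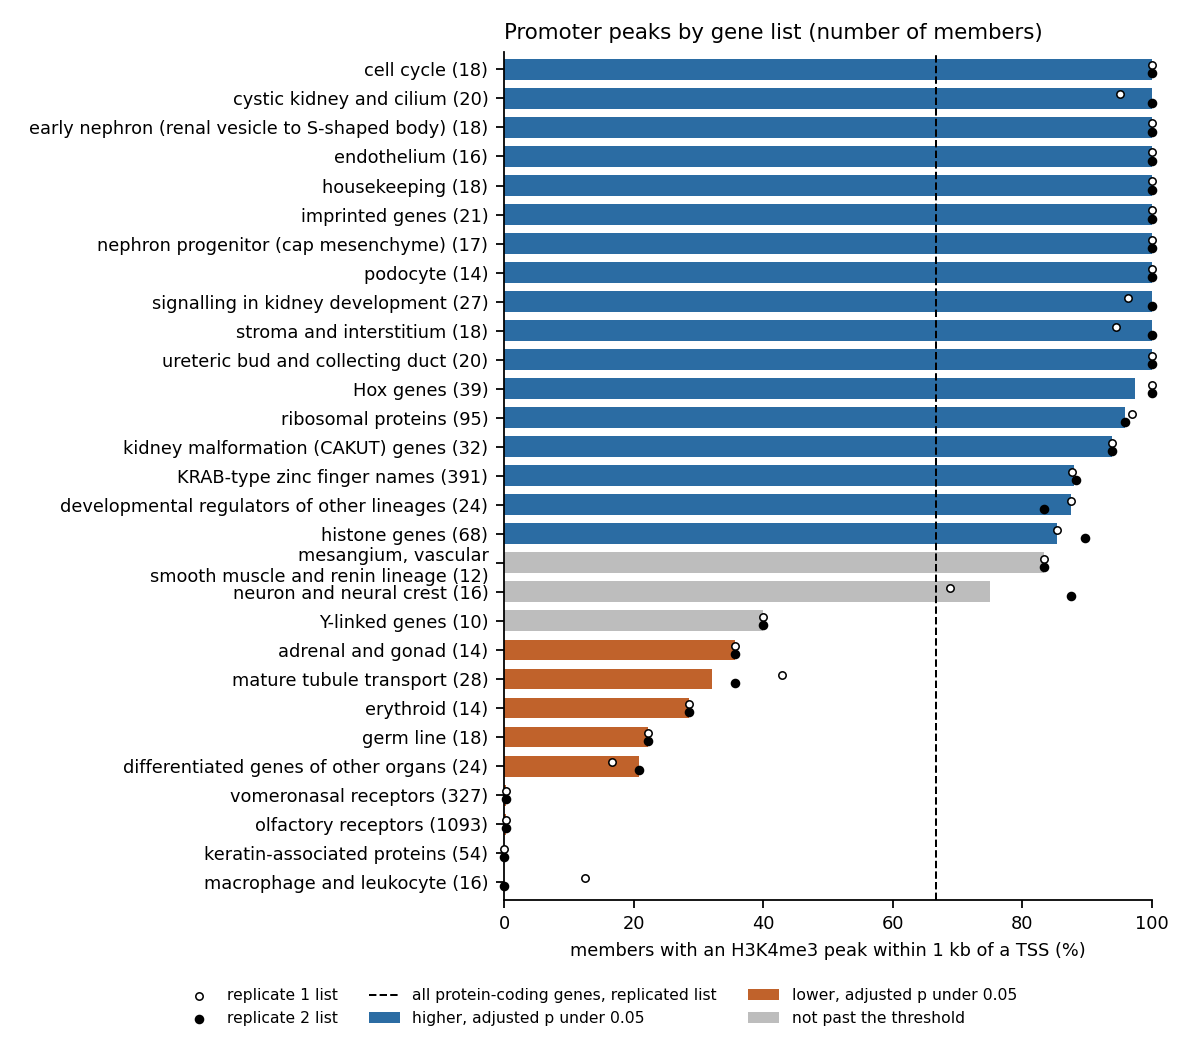
Share of members with a peak within 1 kb of an annotated TSS (x axis, percent) for 29 gene lists (y axis, members in parentheses), with bars for the authors' replicated list, open points for replicate 1, filled points for replicate 2 and a dashed line at the 66.7% of all protein-coding genes. Bars are blue or orange where a list is higher or lower at an adjusted p under 0.05 (Fisher's exact test); the 6 lists named above for kidney cell types reach 100%, and the macrophage and leukocyte list is at 0%.

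Among marked promoters, 10 lists differed from random lists in the height of the peak. In 21 lists tested by the mean log2 signal over both replicates, cell cycle genes (1.30 times the median of random lists) and ribosomal protein genes (1.29 times, highest at Rpl32, Rpl19 and Rps6) had taller peaks. Shorter peaks were found for 8 lists: developmental regulators of other lineages (0.295 times; highest at Gsc, Dlx5 and En2), the mesangium and vascular smooth muscle list (0.308; Notch3, Pdgfb and Mcam), endothelium (0.332), adrenal and gonad (0.350), neurons and neural crest (0.420; Elavl4, Isl1 and Ascl1), mature tubule transport (0.426), histone genes (0.540) and imprinted genes (0.607). Adjusted p of these 10 lists lay between 0.00105 and 0.0311 (two-sided permutation p from 10000 random lists, Benjamini-Hochberg over 21 lists). Nephron progenitor, early nephron and stroma genes (0.893, 0.805 and 0.890 times) and podocyte genes (0.774 times) did not pass the threshold. Ureteric bud genes stood at 0.734 times with an adjusted permutation p of 0.0672, and passed the threshold with the list of replicate 2 alone, with the pooled list, with strong peaks only and against CpG-matched lists. Against CpG-matched lists early nephron genes also passed it as shorter, and genes with KRAB-type zinc finger names as taller. The call of the adrenal and gonad list, with 5 measured members, ended against CpG-matched lists.

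Promoter domains, made by merging peaks up to 1 kb apart, were wide at genes of nephron progenitors, the early nephron and the stroma. The median width of the domain was 7267 bp for 17 nephron progenitor genes (6847 and 7693 bp in replicates 1 and 2), 5120 bp for 18 early nephron genes (4829.5 and 5603 bp), 4813 bp for 18 stroma genes (4801 and 5006.5 bp) and 3490.5 bp for 20 ureteric bud genes (3175 and 3910 bp). It was 2139 bp for all 14639 genes with a promoter domain (quartiles 1577 and 2862.5 bp). Among domains that hold the TSS of 1 protein-coding gene, an alternative added after seeing the data, the nephron progenitor median was 4678 bp over 14 genes, against 1997.5 bp in random lists. Single genes reached 12266.5 ± 6042 bp at Six2 (mean ± SD, n = 2 replicates), 18496.5 ± 658 bp at Pax2, 12271.5 ± 1049 bp at Wt1, 12243.5 ± 544 bp at Sall1, 8719 ± 1138 bp at Eya1, 5889.5 ± 306 bp at Foxd1 and 3625.5 ± 507 bp at Ret. Signalling genes (4284 bp), housekeeping genes (3912 bp), histone genes (3807 bp), imprinted genes (3431 bp), CAKUT genes (3189 bp), podocyte genes (2877.5 bp), cell cycle genes (2861.5 bp), endothelial genes (2826.5 bp), ribosomal protein genes (2790 bp) and Hox genes (26360 bp, but 8271 and 42064 bp in replicates 1 and 2) were also wider than random lists. This made 14 of 22 lists. Mature tubule transport genes (1198 bp, and 755 and 1100.5 bp in replicates 1 and 2) and genes with KRAB-type zinc finger names (1816 bp, and 1658 and 1935 bp) were narrower. Adjusted p of the wider and narrower lists ran from 0.0004 to 0.0465 (two-sided permutation p from 10000 random lists, the smallest possible being 0.0002 before adjustment). Developmental regulators of other lineages had a median of 2421 bp and did not pass the threshold (adjusted permutation p = 0.359). Neither did the cystic kidney, neuron, mesangium, adrenal and gonad, and other-organ lists. The podocyte call ended under 6 of 12 alternatives and the endothelial call under 7, in both cases without replicate 1 (2876.5 and 2998 bp) and for endothelium also without replicate 2 (2056.5 bp). The cell cycle call ended without replicate 1 (2948.5 bp) and the housekeeping call when only the 5′ end of a gene was used. Those of Hox and histone genes ended among domains that hold the TSS of 1 protein-coding gene. When only touching peaks were merged, histone genes (percentile 0.445 among random lists) and developmental regulators of other lineages (percentile 0.03) were narrower. The mesangium and vascular smooth muscle list was narrower without replicate 2 (1148 bp), and the other-organ list without replicate 1 (1210 bp) and with a window of 2.5 kb (percentile 0.33).

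**Figure D3:**
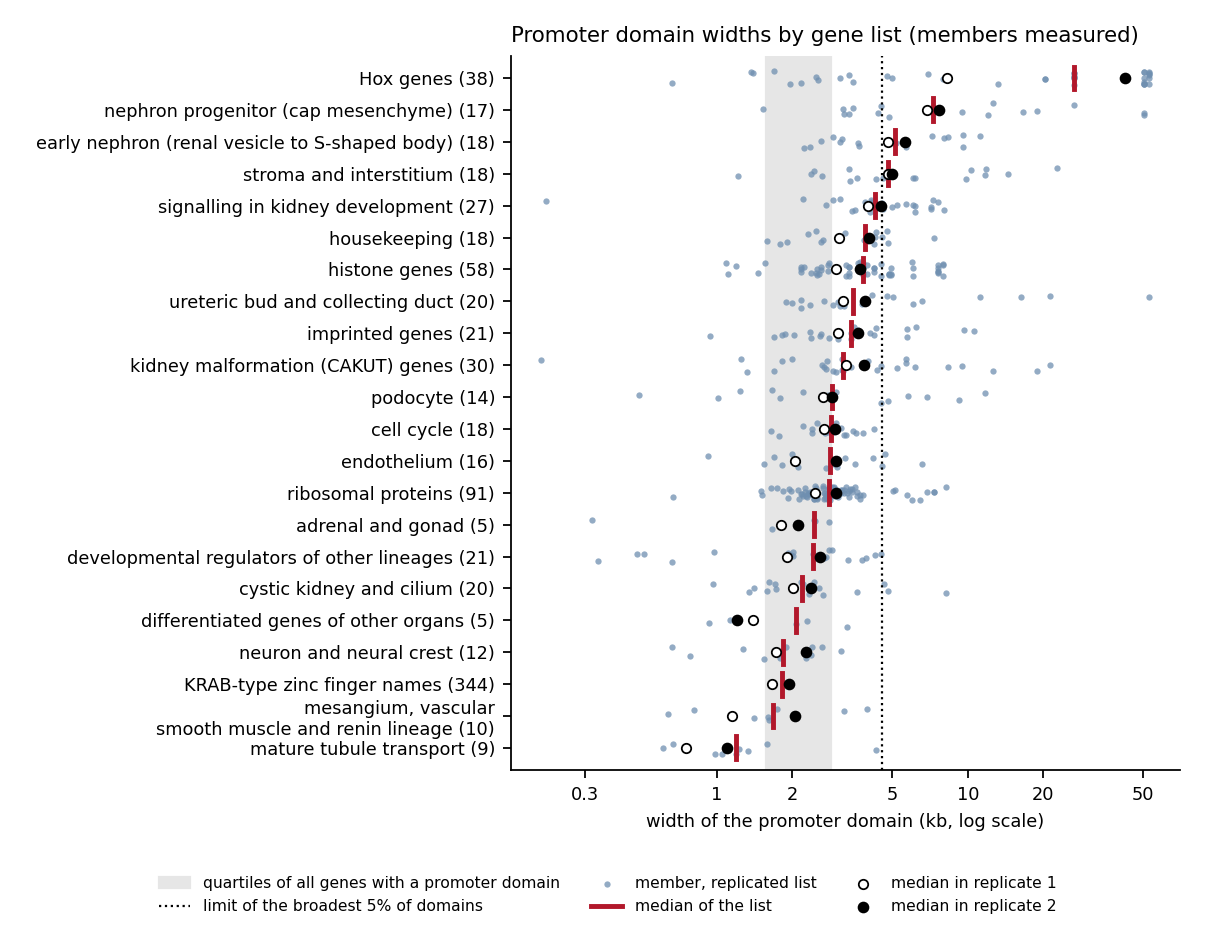
Width of the promoter domain (x axis, kb, log scale) for the members of 22 gene lists (y axis, members measured in parentheses), with 1 small point per member in the authors' replicated list (not drawn for the 344 genes with KRAB-type zinc finger names), a red bar at the list's median and open and filled points at the medians in replicates 1 and 2. The shaded band spans the quartiles of all genes, 1577 to 2862.5 bp, and the nephron progenitor, early nephron and stroma medians lie to its right in both replicates.

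Of the 14 wider lists, 10 were enriched among the broadest domains. The broadest 5% of promoter domains (655 domains of at least 4559 bp, with 820 protein-coding genes) held 10 of 17 nephron progenitor genes, 10 of 18 early nephron genes, 10 of 18 stroma genes, 8 of 20 ureteric bud genes, 5 of 14 podocyte genes, 13 of 27 signalling genes, 9 of 30 CAKUT genes, 5 of 21 imprinted genes, 27 of 38 Hox genes and 17 of 58 histone genes. Of the other genes, 5.43% to 5.58% lay in such domains. Adjusted p of these 10 lists ran from 1.91e-24 to 0.0141 (Fisher's exact test, two-sided, Benjamini-Hochberg over 27 lists). The lowest is that of Hox genes, many of which share a domain, such as the 6 genes from Hoxb3 to Hoxb8. The test counts genes of 1 domain as separate, so its p can be too small. The lists also overlap. Pax2, Eya1, Sall1, Gata3 and Hnf1b, all in the broadest domains, stand both in the CAKUT list and in a kidney cell type list. None of 21 developmental regulators of other lineages and none of 18 cell cycle genes lay in the broadest domains (adjusted p = 0.943 for both, Fisher's exact test). The housekeeping (3 of 18), endothelial (3 of 16) and ribosomal protein lists (9 of 91) did not pass the threshold (adjusted p = 0.172, 0.139 and 0.196, Fisher's exact test). The housekeeping list passed it without replicate 1 and with the pooled list, and the ribosomal protein list without replicate 1. Outside the Hox clusters the broadest domains belonged to Nr2f2 (25637 bp, chromosome 7 at 70345567 to 70371203), Meis2 (22563 bp, chromosome 2 at 116053955 to 116076517), Gata3 with 2 neighbouring gene models (21152 bp, chromosome 2 at 9869272 to 9890423), Pax2 (18928 bp, chromosome 19 at 44746231 to 44765158) and Tbx2 (16602 bp, chromosome 11 at 85828649 to 85845250), all transcription factor genes. In the replicates, the widest domain at these places measured 25753 and 25518 bp, 17009 and 21200 bp, 20671 and 22349 bp, 18031 and 18962 bp, and 16025 and 16688 bp. The imprinted call ended when only the 5′ end of a gene was used and the podocyte and histone calls when only touching peaks were merged. Histone genes, whose TSSs lie close together, had 0% in the broadest domains that hold the TSS of 1 protein-coding gene.

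Hox genes, the homeodomain genes that pattern the body axis and of which the Hox10 and Hox11 paralogs are known to act in the kidney, lay under the 4 widest promoter domains of protein-coding genes in the replicated list, while 11 of 38 marked Hox genes lay outside the broadest 5%. A domain of 52690 bp on chromosome 11 (96276989 to 96329678) covered the annotated 5′ ends of Hoxb3 to Hoxb8. One of 50136 bp on chromosome 6 (52199968 to 52250103) covered those of Hoxa3, Hoxa5 to Hoxa7 and Hoxa9 to Hoxa11. Domains of 26418 bp on chromosome 15 (102958916 to 102985333; Hoxc5, Hoxc9 and Hoxc10) and 26360 bp on chromosome 2 (74674782 to 74701141; Hoxd9 to Hoxd12) followed. A further 20217 bp lay at Hoxd3 and Hoxd4, whose annotated 5′ ends (74711927 and 74711929) were outside it. In replicate 1 all but the domain at Hoxb3 to Hoxb8 fell into several domains, the widest measuring 51451, 35360, 22882, 15793 and 10173 bp. In replicate 2 they measured 60291, 50506, 26478, 42064 and 20217 bp. Genes of paralog groups 1 to 11 had a peak in 33 of 33 cases and those of groups 12 and 13 in 5 of 6 (p = 0.154, Fisher's exact test, two-sided). Peaks of groups 1 to 11 were taller, at a mean log2 signal of 4.67 ± 0.50 (SD over 33 genes) against 2.85 ± 0.85 (6 genes), a difference of 1.82 (p = 1.04e-05, two-sided exact permutation test over 3262623 arrangements). Height counts peaks in both replicate lists, so Hoxc12 is included without a replicated peak. Genes that share a peak share its value, and the permutation test counts them as separate, so its p can be too small. A gene counts by any annotated TSS, so a gene with several TSSs can take the height or width of a neighbour's promoter. At Hoxd11 the signal was 25.9 in replicate 1 and 48.4 in replicate 2, at Hoxd13 it was 11.5 and 20.8, and at Hoxc12 it was 3.58 and 2.65.

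**Figure D4:**
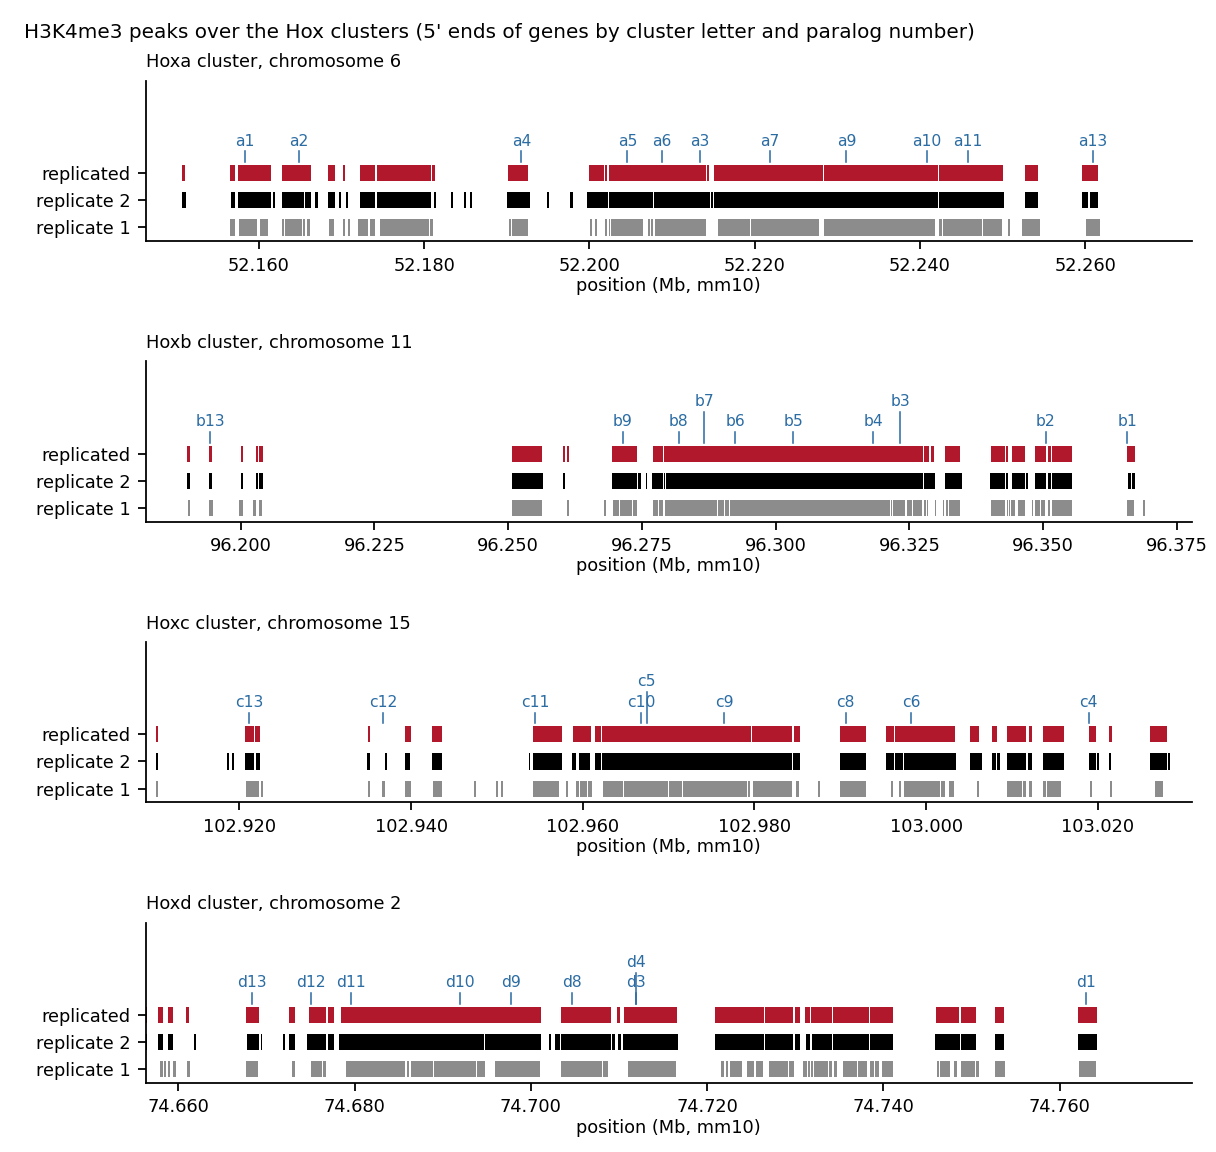
Position of the authors' peaks (bars) over the 4 Hox clusters on mm10 (x axis, Mb) in the replicated list and in replicates 1 and 2, with the 5′ ends of the Hox genes marked above by cluster letter and paralog number. Peaks run almost without a break from Hoxb8 to Hoxb3 and from Hoxa5 to Hoxa11 and are short and isolated at the paralogs of group 13.

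Protein-coding genes on the X chromosome had a promoter peak less often than autosomal genes. The shares were 52.0% (493 of 948) and 68.0% (14142 of 20807), with an odds ratio of 0.511 (p = 2.3e-23, Fisher's exact test, two-sided). Among genes whose symbol is not a Gm number or a Rik clone name, the gap was smaller, at 60.7% (481 of 792) and 71.6% (13626 of 19040). The comparison was not matched on promoter CpG content, which peak presence followed across genes, so its part in the gap was not tested. Of 183 protein-coding Y-linked genes, 17 of them with such a symbol, 4 were marked, Kdm5d, Eif2s3y, Uty and Ddx3y. Their signals ran from 6.67 to 10 in replicate 1 and from 13.8 to 18.4 in replicate 2. Sry and Rbmy had no peak. Xist, the non-coding RNA gene of X inactivation, had a promoter peak in both replicates (6.27 and 15.8), in pools that hold both sexes.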

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

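The comparison within gene families, the setting of domains of 1 gene and the intervals from resampled members were chosen after the widths of the gene lists had been seen. The other tests were set before their results. The data hold 1 group, so no biological explanation was tested for any of these patterns.

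Replicated peaks were also present in a part of the data that no comparison used: 11 lay on unplaced or unlocalised scaffolds.

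The promoter domains of 6 kidney cell type lists (nephron progenitor, ureteric bud, early nephron, stroma, podocyte, endothelium) were wider than those of random lists. Against random lists matched on promoter CpG content, 5 of the 6 stayed past the threshold at percentiles of 99.75 or higher. This argues against the CpG ratio within 1 kb of the 5′ end, in 5 classes, as the cause of their width, except for endothelium. Widths could come from any annotated TSS, and CpG content was not matched at TSSs other than the 5′ end. Matching lowered the median of the endothelial random lists from 2142 to 1818.5 bp. With the 5′ end only, the endothelial widths were at percentile 42.15, so matching at the 5′ end cannot decide there. The length of the CpG-rich stretch was not measured or matched, so its part in the width stays open. The podocyte list fell to 97.235 and its call ended, since the median of its random lists rose from 2141.5 to 2255 bp; its fold over random lists went from 1.34 (95% interval from resampled members 0.776 to 2.70) to 1.28 (0.737 to 2.57), which is too wide a spread to decide. Among domains that hold the TSS of 1 protein-coding gene, the 6 lists stayed at percentiles of 98.265 or higher. This argues against joined promoters of protein-coding genes as the whole cause. Domains that join the promoter of a non-coding gene stay in this setting, so their part was not tested. In the nephron progenitor list, joins of protein-coding promoters may account for part of the width. Without 3 of its 17 members the median fell from 7267 to 4678 bp. The fold went from 3.40 (1.64 to 7.73) to 2.34 (1.69 to 5.52), with overlapping intervals that leave the size of that part open. The lowest percentile was that of endothelium, whose fold went from 1.32 (0.894 to 1.68) to 1.36 (1.00 to 1.79) with 15 of 16 members left, although its adjusted permutation p of 0.0525 misses the threshold; none of the 14 podocyte members was lost.

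Families were taken as genes whose symbols share the stem before the final number, a pattern of names and not of descent. The other members left out genes of the kidney cell type, signalling and CAKUT lists and genes without a promoter domain. Within 39 such families, 54 list members had a median of 1.49 times the width of these others (43 wider, 11 narrower, one-sided permutation p = 0.0001, the smallest possible). The ratio lay between the bounds set for and against family membership, which may therefore account for part of the width. Leaving out relatives that stand in the kidney lists may raise the ratio. The lists differ from random genes in other ways that were not tested, such as transcription in these cells.

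Signal values were higher in replicate 2, by a median of 1.02 on the log2 scale over genes. The median was 0.90 in the lowest 25% of promoters by height and 1.03 in the highest 25%, a difference of 0.13, which is consistent with 1 scale factor for promoter peaks found in both lists; other peaks were not tested, and over all shared peaks the log2 ratio had an SD of 0.89, against 0.32 over genes. Whether that factor comes from read depth, from the efficiency of the precipitation or from the controls stays open, since read numbers were not given in the sources used here.

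Peaks in 1 replicate's list only numbered 5304 in replicate 1 and 8013 in replicate 2. Of those of replicate 1, 1.17% reached a -log10 q of 5, which is consistent with weak peaks near the calling threshold. Of those of replicate 2, 21.1% (1687) reached it and 28.7% lay within 1 kb of a TSS, against 18.9% in replicate 1, so weak peaks are not the whole account there. A lower sensitivity of the replicate 1 library is a candidate explanation that was not tested.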

How the results depend on the processing

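Domains of 1 gene and lists without Hox genes were chosen after seeing the data. The overlap of the replicates, the promoter share (62.5% to 78.7%), the number of genes with a promoter peak (13854 to 14836), the X chromosome's odds ratio (0.490 to 0.539) and the difference between Hox groups (1.49 to 2.15 on the log2 scale) kept their direction and their side of the threshold, or stayed within 1.5 times the main value, in every alternative run. So did the widths of the nephron progenitor, ureteric bud, early nephron, stroma, signalling, CAKUT and imprinted lists. Wider lists numbered 11 to 14 and those enriched among the broadest domains 8 to 12. The following moved, and where no reason is given the cause was not tested. Matching on CpG content left 5 lists higher instead of 17. For nephron progenitor, ureteric bud, early nephron, podocyte, housekeeping, cell cycle and cystic kidney genes, all marked, not even the highest possible share passed there. Matching also put developmental regulators of other lineages (87.5%, percentile 16.7, short of the threshold) and histone genes (85.2941%, percentile 0) below the middle of random lists. With the 5′ end only, the endothelial widths fell to percentile 42.15. Merging only touching peaks put histone genes at percentile 0.445 and developmental regulators of other lineages at 0.03, both then narrower. Among domains of 1 gene 0% of histone genes were in the broadest, since that setting leaves out domains across neighbouring genes. Narrower lists numbered 5 with windows of 2.5 kb and 4 with touching peaks only, instead of 2. Depleted lists among the broadest domains numbered 0 to 1 without replicates 1 or 2. Distal peaks numbered 2580 beyond 10 kb and 7705 to 8108 in the lists of single replicates, instead of 5108. With -log10 q of at least 5, rho was 0.888 over genes and 0.877 over shared peaks, and with signal times width 0.940 over genes. Of 139 named genes' domain widths in the replicated list, 34 lay over 1 SD (of the 2 replicates) from the width without replicate 1, and 78 from that without replicate 2.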

Other observations

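The test of how domains extend from the TSS was set before its result; the genes named in the next paragraphs were chosen after their values were seen.

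Among domains that hold the TSS of 1 protein-coding gene, several of the widest belonged to regulators outside the kidney lists. The T-box gene Tbx3 had a domain of 12292 ± 5435 bp (mean ± SD, n = 2), Sim1 11413.5 ± 3020 bp, Gata2 11456.5 ± 38.9 bp, Gata6 10156.5 ± 1809 bp, Tfap2a 12674.5 ± 1466 bp and Osr2 10090 ± 8.49 bp. Genes of chromatin and signal regulation were there as well: the histone demethylase gene Kdm6b (13391.5 ± 719 bp), the histone methyltransferase gene Setd1b (11497 ± 59.4 bp) and Smad7, an inhibitor of TGF-beta signalling (12790 ± 2.83 bp). Of the long non-coding RNA genes, 701 had a domain over 2.5 kb from every protein-coding TSS, with a median width of 1092 bp, and Malat1 (8170 ± 165 bp) had one of the widest.

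Several members of the kidney lists had wider domains than the median of other genes with the same name stem, chosen as above. The widths that follow are those of the replicated list alone. The domain of Pax2 was 18928 bp and that of Pax8 5174 bp, against a median of 1698 bp at 6 other Pax genes. Six2 had 16521 bp and Six1 3174 bp, against a median of 985 bp at Six3, Six4 and Six6. Lhx1 had 11140 bp against a median of 2614 bp at 7 other Lhx genes, and Eya1 9478 bp against 1982 bp at 3 relatives. Of the Irx genes, Irx3 (9563 bp) and Irx2 (5695 bp) were well above the median of 2013 bp at Irx4, Irx5 and Irx6. In the replicated list Irx1 (2593 bp) was nearer to that median, and its widths in the single replicates were not compared here. The opposite was seen at the endothelial genes Sox17 (2941 bp) and Sox18 (2111 bp), below the median of 3334 bp at 15 other Sox genes. Notch2 (3098 bp) lay between Notch3 (2063 bp) and Notch4 (8557 bp).

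A few domains at genes of other organs, the mature tubule and the vomeronasal organ had the TSS of another gene in them or within 1 kb. This was a TSS of Bmp1 at Sftpc (a surfactant protein gene of the lung) and of Klc3 at Ckm. It was a TSS of Lrrc75b at the tubule gene Ggt1, and of Nt5c3 at the vomeronasal receptor gene Vmn1r4. No other protein-coding TSS lay in the domains of the erythroid genes Klf1, Gypa, Epor and Tal1 or of the germ line genes Dazl, Dmrt1, Tdrd1 and Tdrd6. The 4 imprinted non-coding genes H19, Kcnq1ot1, Airn and Meg3 each had a replicated promoter peak.

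A hypothesis was that the broadest domains extend from the TSS into the gene body. Counted were 468 genes with a broadest domain that holds their 5′ end and the TSS of no other protein-coding gene. Of these, 423 (90.4%, 95% exact binomial interval 87.3% to 92.9%, which treats genes as independent) had a domain reaching farther downstream than upstream of the 5′ end. The medians were 4156 bp downstream and 1339 bp upstream. This share lay above the bound set for the hypothesis. The 5′ end is a gene's outermost annotated TSS, so its other TSSs can only lie downstream. That favours a farther reach downstream, so the share cannot decide the hypothesis. Nor does it set the broadest domains apart, since 93.3% of 9341 other genes, counted by the same rule, showed the same. Pax2 was an exception with 9814 bp upstream and 9113 bp downstream.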
